A study of Mus musculus with 12 samples.

How the data were processed

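Gene expression was measured on an Affymetrix mouse array in cells sorted from colon adenomas of 3 mice. Per the labels, cells were sorted by Mex3a status and Lgr5 status into 4 populations, and each mouse gave 1 array per population, so the 12 arrays form 4 groups of 3. The replicates are mice, each a pool of adenoma cells: 500 sorted cells per pool for mouse MKL358 and 2000 for mice MKL347 and MKL367. The labels write ki/+ for every mouse without saying what it stands for. Per the labels, 25 ng of total RNA went through a whole transcriptome amplification and 8 µg of the cDNA was labelled.

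The deposited values are log2 signals, made by RMA per the submitters' processing notes; the software, version and options are not given in the sources used here. They were used as deposited. The array holds 45141 probe sets. GEO's platform table gives 1 gene symbol to 28898 of them, several to 551 and none to 15588, and 104 are Affymetrix controls. Probe sets with several symbols or none were left out of the gene tests and were tested separately. That test was added after the data files had been opened. For the 7180 of 17097 symbols with more than 1 probe set, the probe set with the highest mean over the 12 arrays was used. Genes were kept if they exceeded the 40th percentile of all values (4.40 on the log2 scale) on at least 3 arrays, which left 12595. No coordinates were used. The number of arrays limits the precision.

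Each gene was fitted with limma 3.58.1 in R 4.3.3, with 1 mean per group over all 12 arrays, an empirical Bayes step with an intensity trend, and 2-sided tests. Genes with a Benjamini-Hochberg adjusted p under 0.05 over the 12595 genes were called. Every adjusted p for a gene in the text is limma's, and every error is limma's standard error. The 9 comparisons were the average effects of Mex3a status and of Lgr5 status (6 arrays against 6), each effect within each state of the other marker, double positive against double negative cells, the single positive populations against each other (3 against 3), and the interaction. The main fit left out the pairing of arrays by mouse, and the fit with the mouse as a block was the first alternative. The median standard error of the average Mex3a effect was 0.0901 in the main fit and 0.0718 with the block. A gene not called by the main fit may thus pass once the pairing enters. Gene calls without 1 mouse or 1 array come from the main fit unless stated otherwise. The mouse number in the sample titles gave the pairing. After the group means were removed, arrays of the same mouse correlated at 0.349 to 0.694 across genes (18 pairs), and arrays of different mice at -0.691 to 0.152 (48 pairs).

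The gene lists (36, of which 35 had at least 5 measured genes) came from general knowledge; 785 of their 1023 genes were measured. They were tested with limma's camera with a preset correlation of 0.01 between genes, adjusted over the lists within a comparison. Camera with an estimated correlation and fry were run beside it. Fry tests whether the genes of a list move, on balance, one way, and compares them with no other genes. Adjusted p-values for lists are camera's with the preset correlation unless stated otherwise. The named genes were chosen by a rule: for both average effects and for the Mex3a effect in Lgr5-positive cells, the 12 largest rises and 12 largest falls among called genes with the same sign in all 3 mice, filled from the fit with the mouse as a block where fewer passed; for the other comparisons up to 5 per direction; Mex3a and Lgr5 everywhere; and the 4 members with the smallest p of each list described. Symbols of clones, gene models and expressed tags were replaced by the next gene. The groups, lists, tests, named-gene rule and alternatives were fixed before the data were examined, except where the text says otherwise.

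The alternatives were the mouse as a block, no filter, a filter at the 60th percentile, a further quantile normalization, median centring of each array, the mean of all probe sets of a gene, every probe set on its own, the empirical Bayes step without the trend, array weights, and leaving out each mouse and each array. Added after the data had been seen were the mouse as a random effect and, for the lists, the block together with an estimated correlation. So were fits without each array for the lists and for the genes called with the block but not in the main fit. The gene test was checked on simulated data with 200 changed genes among the 12595, with the spread and the mouse differences of the real arrays. For the average Mex3a effect it recovered 66.7% of the genes changed by a log2 difference of 0.5, 93.5% at 1 and 100% at 2, with 0 false calls; with the mouse as a block the shares were 91.3%, 100% and 100%, with 12 false calls. For the Mex3a effect in Lgr5-positive cells it recovered 31.9%, 83.9% and 100% with 0 false calls, and 68.1%, 100% and 100% with 10 false calls with the block. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.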

Results

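The data comprised 12 arrays from colon adenoma cells of 3 mice, sorted into Mex3a+ Lgr5+, Mex3a+ Lgr5-, Mex3a- Lgr5+ and Mex3a- Lgr5- populations, with 3 arrays per population. Mex3a encodes an RNA-binding protein, and Lgr5 a receptor that marks stem cells at the base of intestinal crypts. The median log2 signal of an array lay between 4.86 and 4.92. Arrays of the same population correlated at 0.984 to 0.994 across probe sets, which are not independent replicates. The first principal component held 56.4% of the variance and parted the Mex3a+ from the Mex3a- arrays. The second held 16.6% and set the 4 arrays of mouse MKL358, whose pools had 500 cells, apart from the rest.

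The transcripts of both sorted markers followed the labels. Mex3a was 1.61-fold higher in Mex3a+ than in Mex3a- cells (log2 difference 0.69, SE 0.12, 6 arrays against 6, limma adjusted p = 0.00162), and higher in each of the 3 mice. Lgr5 was 2.92-fold higher in Lgr5+ than in Lgr5- cells (log2 difference 1.55, SE 0.14, limma adjusted p = 0.000872). Lgr5 was also 1.76-fold higher in Mex3a+ than in Mex3a- cells (0.82, SE 0.14, limma adjusted p = 0.00139). The Mex3a transcript had a log2 difference of 0.22 (SE 0.12) between Lgr5+ and Lgr5- cells, which did not pass the test (limma adjusted p = 0.924). Another probe set of each gene, dimmer on average, gave smaller differences. These were 0.34 for Mex3a by Mex3a status, 1.24 for Lgr5 by Lgr5 status, 0.61 for Lgr5 by Mex3a status and -0.034 for Mex3a by Lgr5 status (limma adjusted p over all probe sets 0.0461, 0.00253, 0.00493 and 0.9996). Without mouse MKL347 all of these effects lost their call, at a limma adjusted p of 0.0615 for Mex3a and 0.0664 for Lgr5 by Mex3a status, and 0.258 for Lgr5 by Lgr5 status.

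**Figure D1:**
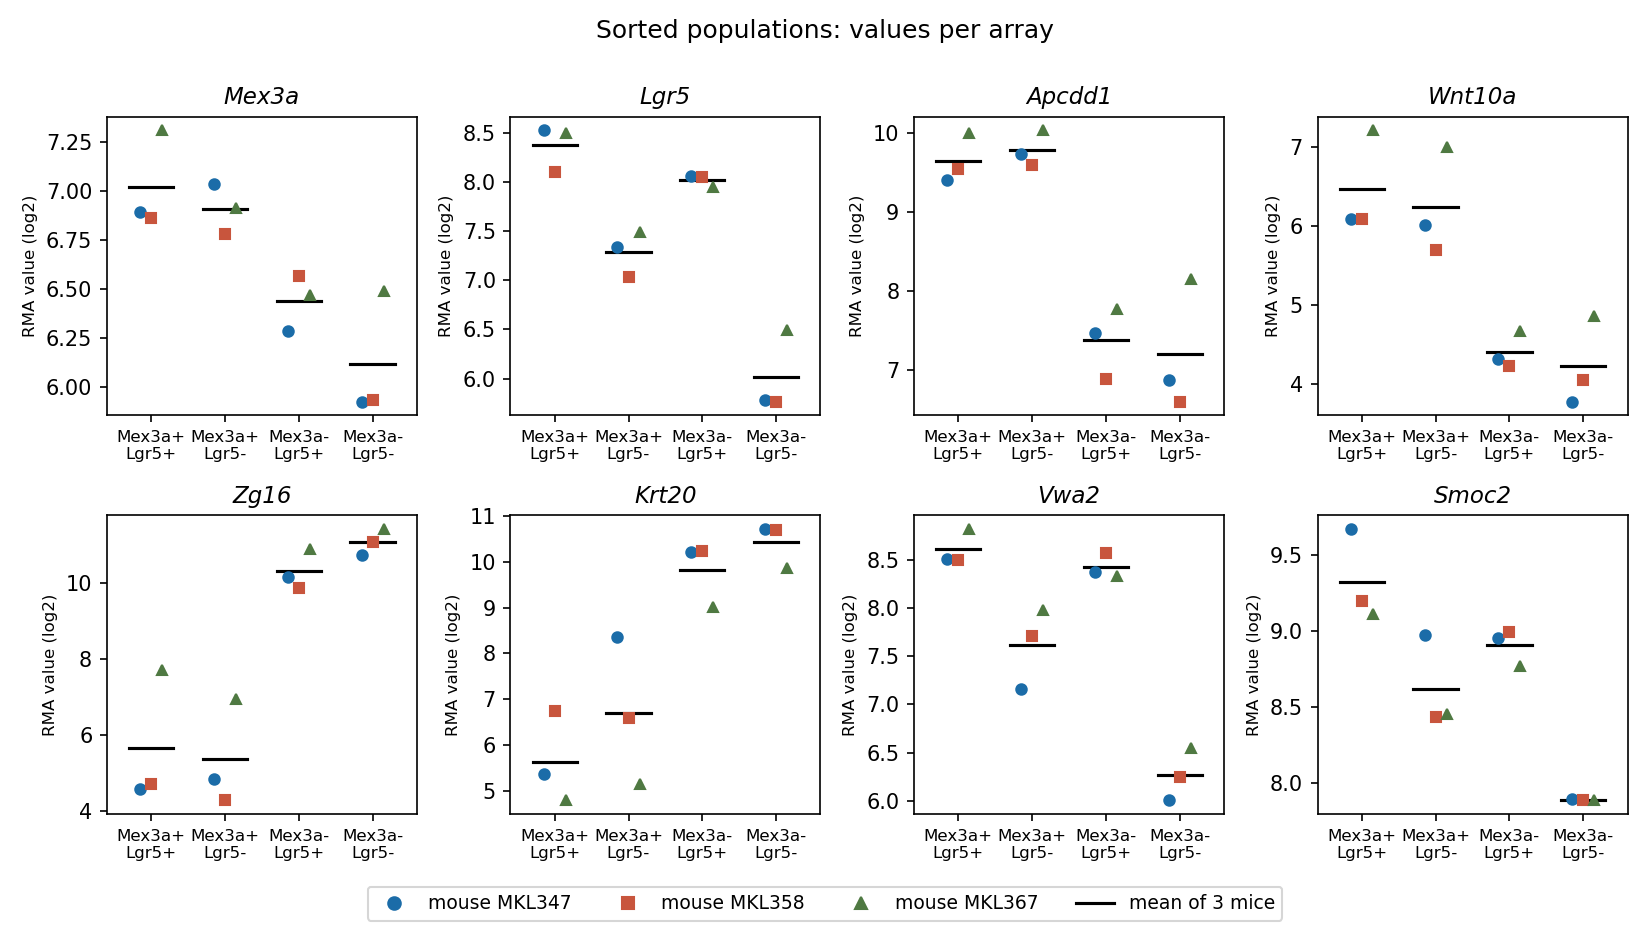
RMA values (log2, vertical axis) of 8 genes on each array of the 4 sorted populations, with 1 symbol per mouse and a bar for the mean of 3 mice. Apcdd1 lay between 9.40 and 10.03 on the Mex3a+ arrays and between 6.60 and 8.15 on the Mex3a- arrays, and Zg16 between 4.27 and 7.72 against 9.87 to 11.44.

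The average Mex3a effect asked how Mex3a+ adenoma cells differed from Mex3a- cells at either Lgr5 status (6 arrays against 6). Genes of mature colon epithelium were far lower in Mex3a+ cells: Zg16, which encodes a protein of goblet cell granules, was 36.6-fold lower (log2 difference -5.19, SE 0.57; -3.82, SE 0.22, by its other probe set), Krt20, a keratin of mature surface cells, 15.6-fold lower (-3.96, SE 0.50), Slc26a3, a chloride and bicarbonate exchanger of colonocytes, 14.7-fold lower (-3.88, SE 0.29), and Car1, a carbonic anhydrase, 9.32-fold lower (-3.22, SE 0.17). The gasdermin gene Gsdmc2 was lower (-4.92, SE 0.23), with means of 3.30 and 3.39 in the Mex3a+ populations, below the filter's level of 4.40. Apcdd1, a Wnt target that encodes an inhibitor of the pathway, was 5.37-fold higher (2.42, SE 0.25), and the Wnt ligand gene Wnt10a was higher (2.04, SE 0.27), with means of 4.41 and 4.23 in the Mex3a- populations, about the filter's level. The pancreatic lipase-related genes Pnliprp1 and Pnliprp2 and the albumin gene Alb were 6.29-fold (2.65, SE 0.48), 5.55-fold (2.47, SE 0.35) and 5.13-fold (2.36, SE 0.29) higher. Each of these genes had a limma adjusted p of 0.00183 or less, and the rule that chose them required the same sign in 3 of 3 mice.

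The other large rises were Mt4 and Mt3 (metallothioneins), Adam12 (a metalloprotease), Ltbp1 (a TGF-beta binding protein), Erich3, Plagl1 (a zinc finger factor) and Tubb4a (a tubulin), with log2 differences between 2.01 and 2.26. The other large falls were Saa1 and Saa2 (serum amyloid A), Muc3 (a membrane mucin), Aqp4 (a water channel), Reg3b (an antimicrobial lectin), Dmbt1 (a mucosal defence protein) and Clca4a, with log2 differences between -4.41 and -3.25. In all, 1248 genes were higher and 2174 lower in Mex3a+ cells by limma, of which 153 and 253 by at least 2-fold, and 3415 of the 3422 had the same sign in 3 of 3 mice. With the mouse as a block, 2000 were higher and 3192 lower. The lower share of the calls was 63.5%, and 53.6% after a further quantile normalization or 50.9% after median centring. Without mouse MKL347 the count was 1034 and without mouse MKL367 it was 1546. Without mouse MKL347 the calls of Pnliprp1 (limma adjusted p = 0.0747), Mt4 (0.0967), Erich3 (0.120) and Saa2 (0.0523) were lost, and without mouse MKL358 that of Mt4 (0.0681).

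Colonocyte genes fell: of 34 measured, 25 were lower, 2 higher and 7 did not pass (27 lower and 2 higher adjusted over the list alone), with a median log2 difference of -1.18. Ceacam20 (-2.91), Fabp2 (-3.19), Car1 and Slc26a3 had the smallest p (camera adjusted p = 1.71e-12; adjusted p = 0.234 with an estimated correlation). Goblet cell genes fell as well, 23 of 27 lower, 0 higher and 4 not passing (23 lower adjusted over the list alone), with a median of -0.95. Their examples were Capn9 (-0.91), Klk1 (-2.75), Zg16 and Creb3l1 (-1.34) (camera adjusted p = 5.36e-10; adjusted p = 0.147 with an estimated correlation). Genes of epithelium in general moved less, with a median of -0.27: 17 of 26 were lower, 1 higher and 8 did not pass (17 and 1 adjusted over the list alone), among them Vil1 (-1.06), Hnf4a (-0.71) and Cdx1 (-1.31) (camera adjusted p = 0.000112; adjusted p = 0.400 with an estimated correlation). Beside these falls, markers of other cell types had median log2 differences of -0.08 (macrophages and other myeloid cells), -0.20 (neutrophils), 0.04 (lymphocytes), -0.02 (fibroblasts and smooth muscle) and 0.09 (endothelium) over all probe sets without the filter. By limma 4 of the 31 fibroblast genes were higher and 1 lower, 3 of the 25 endothelial genes higher and 1 lower, and 1 of the 20 neutrophil genes higher and 1 lower. Of the 28 myeloid genes 4 were lower and 0 higher, and after the filter their mean difference was -0.31, larger than their median. Single arrays also stood apart behind these medians. Relative to each gene's mean over the 12 arrays, fibroblast genes had a mean level of 0.76 on the Mex3a- Lgr5+ array of mouse MKL367 and between -0.27 and 0.13 on the other 11. Neutrophil genes had 0.80 and 1.26 on the Mex3a- arrays of mouse MKL358, against -0.17 and 0.18 on its Mex3a+ arrays. After the filter the endothelial genes rose, with 4 of 20 higher, 1 lower and 15 not passing (4 and 1 adjusted over the list alone). Prox1 (1.42), which is also on the list of Wnt targets, and Flt1 (1.08) were among them. The endothelial list had a camera adjusted p of 0.0364, and of 0.400 with an estimated correlation. Without mouse MKL358 its adjusted p was 0.0774, and the call was also lost without either Mex3a+ array of that mouse or either Mex3a- array of mouse MKL347 (0.0583 to 0.0742).

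Wnt targets and feedback regulators rose: 19 of 32 were higher, 2 lower and 11 did not pass (19 and 2 adjusted over the list alone), with a median log2 difference of 0.51 and a rise of that median in 3 of 3 mice. Apcdd1, Axin2 (0.67), Prox1 (1.42) and Wnt10a had the smallest p (camera adjusted p = 6.74e-07; adjusted p = 0.400 with an estimated correlation). Genes of crypt base stem cells split, with 11 of 31 higher, 7 lower and 13 not passing (12 and 8 adjusted over the list alone). Their median was 0.10 and their mean -0.09, and the list was not called (camera adjusted p = 0.180). Axin2 was among the higher members, and Aqp4, Tspan8 (-1.31) and Clca4a, a water channel, a tetraspanin and a member of a chloride channel regulator family, were among the lower.

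Respiratory chain genes fell: 30 of 35 were lower, 0 higher and 5 did not pass (33 lower adjusted over the list alone), with a median of -0.30. Cyc1 (-0.51), Ndufa9 (-0.58) and Sdhb (-0.46) had the smallest p, and the call held with an estimated correlation but not with the mouse as a block as well (camera adjusted p = 2.52e-12; adjusted p = 0.0484 with an estimated correlation; 0.123 with both). Genes of the G2 and M phases of the cell cycle fell, 21 of 36 lower, 0 higher and 15 not passing (24 lower adjusted over the list alone), with a median of -0.27. Birc5 (-0.51), Ccna2 (-0.50), Ccnb2 (-0.54) and Racgap1 (-0.54) led them (camera adjusted p = 3.70e-07; adjusted p = 0.244 with an estimated correlation). The difference between 3' and 5' control probe sets, after amplification a limited sign of RNA integrity, was 0.01 between Mex3a+ and Mex3a- arrays (log2, mean over 3 mice). DNA replication genes had 7 of 38 lower, 1 higher and 30 not passing (6 lower and 0 higher adjusted over the list alone), with a median of -0.18, and Rrm2 (-0.42) and Rrm1 (-0.38) had the smallest p (camera adjusted p = 0.0161; adjusted p = 0.657 with an estimated correlation). The DNA replication list had an adjusted p of 0.0795 without mouse MKL347, 0.0831 without mouse MKL367 and 0.0742 without the Mex3a- Lgr5- array of mouse MKL347. Rrm2 had 0.0932 and 0.0988, and Rrm1 0.0931 and 0.0664.

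Transporters and enzymes of drug handling fell: 14 of 21 were lower, 1 higher and 6 did not pass (14 and 1 adjusted over the list alone), with a median of -0.55. Abcg2 (-1.11), Abcc3 (-1.82) and Abcb1a (-1.23), which encode efflux pumps, had the smallest p (camera adjusted p = 0.000112; adjusted p = 0.349 with an estimated correlation). Genes of ribosome production fell, 13 of 36 lower, 0 higher and 23 not passing (16 lower adjusted over the list alone), with a median of -0.21, among them Nhp2 (-0.33) and Wdr12 (-0.49) (camera adjusted p = 0.000112; adjusted p = 0.400 with an estimated correlation). Ribosomal protein genes had 8 of 37 lower, 0 higher and 29 not passing (7 lower adjusted over the list alone), with a median of -0.10, among them Rpl13 (-0.33) and Rpl24 (-0.21) (camera adjusted p = 0.0159; adjusted p = 0.657 with an estimated correlation). After either scaling 2 of these 37 were lower. Cholesterol synthesis genes had 6 of 19 lower, 0 higher and 13 not passing (8 lower and 1 higher adjusted over the list alone), with a median of -0.18, among them Sqle (-0.60) and Ebp (-0.49) (camera adjusted p = 0.0226; adjusted p = 0.400 with an estimated correlation). Without mouse MKL367 the ribosomal protein list had an adjusted p of 0.194, Wdr12 0.123 and Rpl24 0.100, and without mouse MKL347 Rpl24 had 0.0666. The cholesterol list had 0.0543 without the Mex3a+ Lgr5+ array of mouse MKL347.

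**Figure D2:**
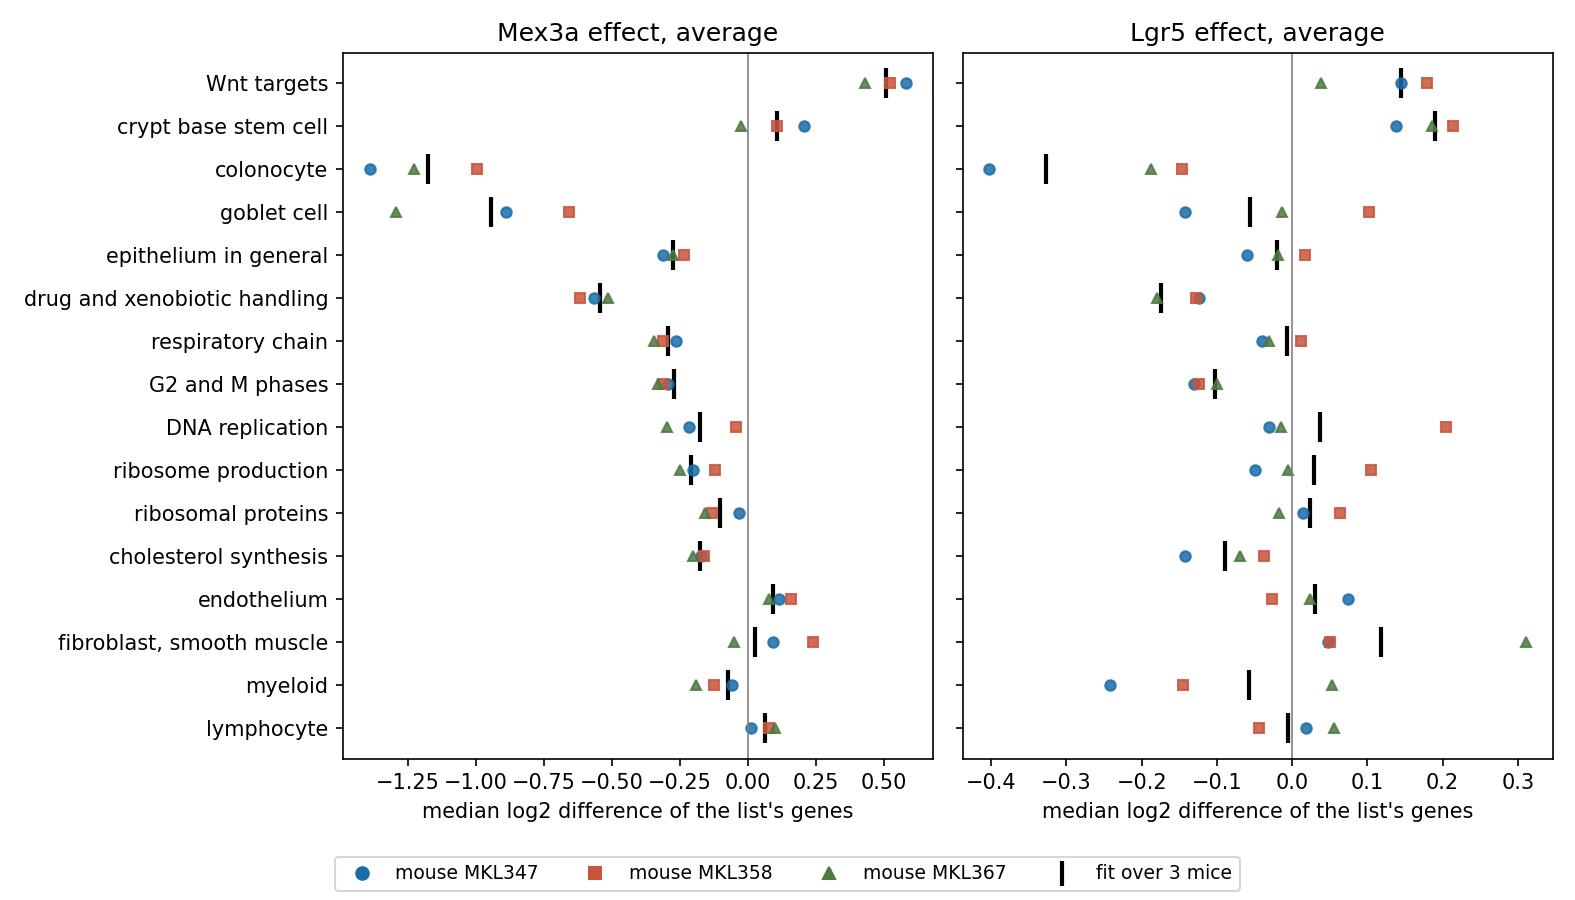
Median log2 difference (horizontal axis) of the genes of 16 lists for the average Mex3a effect (left) and the average Lgr5 effect (right), with 1 symbol per mouse and a bar for the fit over 3 mice; the 2 axes differ in scale. For the Mex3a effect the bars lay at 0.51 for Wnt targets, -1.18 for colonocyte genes and -0.95 for goblet cell genes; for the Lgr5 effect they lay at 0.19 for crypt base stem cell genes and -0.33 for colonocyte genes.

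The average Lgr5 effect compared Lgr5+ with Lgr5- cells at either Mex3a status (6 arrays against 6). Besides Lgr5 itself, Vwa2, which encodes an extracellular matrix protein, was 2.98-fold higher in Lgr5+ cells (log2 difference 1.58, SE 0.14, limma adjusted p = 0.000872). Scara3, a scavenger receptor gene, was higher (0.90, SE 0.10, limma adjusted p = 0.00445), with means of 4.15 and 3.46 in the Lgr5- populations and 4.37 in Mex3a- Lgr5+ cells, below the filter's level of 4.40. Smoc2, a gene of crypt base stem cells, was 1.82-fold higher (0.86, SE 0.12, limma adjusted p = 0.0248). Car1 was 2.49-fold lower (-1.31, SE 0.17, limma adjusted p = 0.0237). These 4 rises and 1 fall had the same sign in 3 of 3 mice and were the only calls by limma, with 783 genes at an unadjusted p under 0.05. With the mouse as a block, 148 genes were higher and 79 lower. By that fit the largest further rises were Muc1, Thbs2, Cxcl13, Prkd1, Fxyd6, Prelp, Sfrp2 and Cdo1 (log2 differences between 0.77 and 1.04). The largest further falls were Trim30d, Nlrp9b, Prss30, Cyp2d34, Slc26a3, Mal, Mylk, Pde9a, Fam3b, Sox17 and Kcnk6 (between -0.80 and -0.66). Without mouse MKL347 there were 0 calls (limma), and without mouse MKL358 or mouse MKL367 there were 3.

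Leaving out 1 array also moved these few calls. The count was 3 without any 1 of the Mex3a- Lgr5+ arrays of mice MKL358 and MKL367, the Mex3a- Lgr5- arrays of mice MKL358 and MKL367 or the Mex3a+ Lgr5- array of mouse MKL367. Vwa2 had a limma adjusted p of 0.129 without mouse MKL347 and 0.129 without mouse MKL358, and Scara3 had 0.164, 0.158 and 0.0525 without mice MKL347, MKL358 and MKL367. Smoc2 had 0.129, 0.237 and 0.456 without these mice, and kept its call without any 1 of the 3 Mex3a+ Lgr5+ arrays or the Mex3a+ Lgr5- array of mouse MKL347 but not without any other array (0.0701 to 0.111). Car1 had 0.331 without mouse MKL347 and 0.549 without mouse MKL367, and kept its call without the Mex3a+ arrays of mouse MKL358 or the Mex3a+ Lgr5- array of mouse MKL347 but not without any other array (0.0522 to 0.0807). Thbs2 had 0.0214 without mouse MKL358 and 0.0281 without its Mex3a+ Lgr5- array, and Cdo1 0.0153 without the Mex3a+ Lgr5+ array of mouse MKL358. With the mouse as a block, leaving out 1 array gave 94 to 277 calls against 227. The 8 further rises kept their call in that fit without any 1 array. Of the falls only Nlrp9b and Kcnk6 did; the others lost it without at least 1 array (0.0520 to 0.134).

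Genes of crypt base stem cells rose with Lgr5 status as a list. Of 31 measured, 1 was higher, 0 lower and 30 did not pass (4 higher and 0 lower adjusted over the list alone, and 7 higher with the mouse as a block), with a median log2 difference of 0.19. Beside Smoc2, the members with the smallest p were Cdk6 (0.47), Rgmb (0.54) and Axin2 (0.29), which did not pass over all genes (camera adjusted p = 6.95e-07; adjusted p = 0.0465 with an estimated correlation, and 0.138 with the mouse as a block as well). Colonocyte genes fell as a list, with a median of -0.33: 1 of 34 was lower, 0 higher and 33 did not pass (4 lower and 0 higher adjusted over the list alone), and after Car1 the smallest p belonged to Car2 (-0.62) (camera adjusted p = 9.19e-11; adjusted p = 0.242 with an estimated correlation). Genes of the G2 and M phases also fell as a list, with a median of -0.10 and 0 of 36 passing by limma singly or adjusted over the list alone (camera adjusted p = 8.53e-08; adjusted p = 0.242 with an estimated correlation). In all, 13 lists were called, 4 up and 9 down, and the stem cell list alone kept its call with an estimated correlation and by fry; with the mouse as a block and an estimated correlation 0 lists were called by camera.

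Markers of stromal and immune cells were among these 13 lists. Fibroblast and smooth muscle genes rose with Lgr5 status, with a median of 0.12 and 0 of 18 passing by limma (2 higher adjusted over the list alone; camera adjusted p = 0.00583; adjusted p = 0.396 with an estimated correlation). That call was lost without mouse MKL367 (median 0.036, adjusted p = 0.4999) and without its Mex3a- Lgr5+ array alone (median -0.0035, adjusted p = 0.553), and held without any other array. Thbs2, Prelp and Sfrp2, among the rises named above, are typical of fibroblasts. Neutrophil genes fell, with a median of -0.21 (camera adjusted p = 0.0449; adjusted p = 0.717 with an estimated correlation), and so did myeloid genes, with a median of -0.057 (camera adjusted p = 0.0399; adjusted p = 0.602 with an estimated correlation). By limma 0 of their 11 and 15 measured genes passed. The neutrophil list lost its call without mouse MKL347 (0.0943) and without 8 of the 12 arrays (0.0515 to 0.988), and the myeloid list without mouse MKL347 (0.559), mouse MKL358 (0.0885) and 6 of the 12 arrays (0.0528 to 0.453).

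Genes with a difference by Lgr5 status tended to differ the same way by Mex3a status. With the mouse as a block, 98 of the 148 genes higher in Lgr5+ cells were also higher in Mex3a+ cells (23.5 if independent) and 16 were lower (37.5 if independent). Of the 79 genes lower in Lgr5+ cells, 69 were also lower in Mex3a+ cells (20 if independent) and 3 were higher (12.5 if independent). Both sets of calls come from the same arrays and share each gene's estimate of spread. The counts if independent may therefore be too low a baseline. Across genes, which are not independent replicates, the average Mex3a and Lgr5 effects correlated at r = 0.512 and rho = 0.389. Simulated arrays without any effect gave a mean r of 0.110, between 0.0423 and 0.191 over 100 draws. Their genes were drawn independently of each other and without differences between mice, unlike those of the real arrays. The simulated range therefore cannot show whether 0.512 exceeds chance.

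The Mex3a effect in Lgr5+ cells compared Mex3a+ Lgr5+ with Mex3a- Lgr5+ cells (3 arrays against 3), which asks what Mex3a status adds among cells with the stem cell marker. Zg16 was 25.1-fold lower (log2 difference -4.65, SE 0.80), Krt20 18.3-fold lower (-4.19, SE 0.71) and Car1 14.6-fold lower (-3.87, SE 0.25). Gsdmc2 was lower (-4.56, SE 0.32), with a mean below the filter's level in Mex3a+ Lgr5+ cells. Alb was 6.03-fold higher (2.59, SE 0.42), Apcdd1 4.83-fold higher (2.27, SE 0.35), and Wnt10a was higher as well (2.06, SE 0.38). The other large rises were Pnliprp1, Pnliprp2, Ltbp1, Mt3, Prex2 (a Rac exchange factor), Slc19a3 (a thiamine transporter), Cd244a, Adam12 and Plagl1. The other large falls were Saa1, Saa2, Reg3b, Aqp4, Muc3, Dmbt1, Slc26a3 and Fabp2. The Mex3a transcript was 0.58 higher (SE 0.17), which did not pass (limma adjusted p = 0.0579) but did with the mouse as a block (limma adjusted p = 0.00851), without the Mex3a+ Lgr5+ array of mouse MKL358 (0.0491) and without the Mex3a- Lgr5- array of mouse MKL367 (0.0300). Lgr5 had a log2 difference of 0.36 (SE 0.20, limma adjusted p = 0.318).

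By limma 404 genes were higher and 605 lower in Mex3a+ Lgr5+ than in Mex3a- Lgr5+ cells; with the mouse as a block the counts were 1114 and 1658. The lower share of the calls was 60%, and 53.3% after a further quantile normalization or 51.3% after median centring. Without mouse MKL347 the count was 19 and without mouse MKL367 it was 183. It was 212 without the Mex3a- Lgr5+ array of mouse MKL358, 213 without that of mouse MKL347, 241 without the Mex3a+ Lgr5+ array of mouse MKL347 and 222 without that of mouse MKL367. Of the 24 named genes, 19 lost their call without mouse MKL347 (limma adjusted p between 0.0801 and 0.424), 4 without mouse MKL358 (0.0507 to 0.128) and 3 without mouse MKL367 (0.0727 to 0.151). These fits held 1 mouse fewer and no pairing by mouse, so a lost call can reflect a larger error as well as a smaller difference. Gsdmc2, Car1, Aqp4, Dmbt1 and Slc26a3 kept their call without any 1 mouse or any 1 array. Among single arrays, the Mex3a- Lgr5+ arrays of mice MKL358 and MKL347 decided 8 of the 24 calls each (up to 0.152 and 0.123 without them), and the Mex3a+ Lgr5+ arrays of mice MKL347 and MKL367 decided 6 and 5 (up to 0.152 and 0.146). Of the remaining arrays, the Mex3a+ Lgr5- array of mouse MKL347 decided 2 (up to 0.0567), and 1 call each rested on the Mex3a+ Lgr5+ array of mouse MKL358 (0.0710), the Mex3a- Lgr5- array of mouse MKL347 (0.0545), and the Mex3a+ Lgr5- (0.0502), Mex3a- Lgr5+ (0.0754) and Mex3a- Lgr5- (0.0527) arrays of mouse MKL367.

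Within Lgr5+ cells, colonocyte genes fell with Mex3a status, 22 of 34 lower, 0 higher and 12 not passing (23 lower and 2 higher adjusted over the list alone), with a median of -0.97, Car1 and Slc26a3 among the 4 smallest p (camera adjusted p = 2.13e-15; adjusted p = 0.114 with an estimated correlation). Goblet cell genes fell, 9 of 27 lower, 0 higher and 18 not passing (17 lower adjusted over the list alone), with a median of -0.81, led by Zg16 (camera adjusted p = 1.44e-08; adjusted p = 0.114 with an estimated correlation). Wnt targets rose, 14 of 32 higher, 0 lower and 18 not passing (18 higher and 2 lower adjusted over the list alone), with a median of 0.49, Apcdd1 and Wnt10a among the 4 smallest p (camera adjusted p = 1.44e-06; adjusted p = 0.423 with an estimated correlation). Respiratory chain genes fell, 17 of 35 lower, 0 higher and 18 not passing (27 lower adjusted over the list alone), with a median of -0.27 (camera adjusted p = 3.58e-11; adjusted p = 0.0656 with an estimated correlation). Genes of the G2 and M phases fell, 11 of 36 lower, 0 higher and 25 not passing (18 lower adjusted over the list alone), with a median of -0.34 (camera adjusted p = 3.85e-10; adjusted p = 0.114 with an estimated correlation). Cyc1 (-0.47) and Ndufa9 (-0.53) of the respiratory chain had a limma adjusted p of 0.128 each without mouse MKL347 and of 0.0761 and 0.0796 without mouse MKL367. Ccnb2 (-0.59) and Ccna2 (-0.49) of the G2 and M phases had 0.176 and 0.212 without mouse MKL347, 0.115 and 0.0800 without mouse MKL367, and 0.0519 and 0.0554 without the Mex3a- Lgr5+ array of mouse MKL358 and of mouse MKL347. Immediate early and heat shock genes that tissue dissociation raises were called in this comparison, with 3 of 27 higher, 0 lower and 24 not passing (4 higher adjusted over the list alone) and a median of 0.20 (camera adjusted p = 0.0226; adjusted p = 0.669 with an estimated correlation). Without the Mex3a+ Lgr5+ array of mouse MKL358 their adjusted p was 0.177, and without the Mex3a- Lgr5+ array of mouse MKL367 it was 0.123. In all, 3 lists were called up and 9 down, and 0 kept the call with an estimated correlation; 8 were called by fry.

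In Lgr5- cells (3 arrays against 3), Zg16 was 53.2-fold lower with Mex3a status (log2 difference -5.73, SE 0.80) and Slc26a3 20.8-fold lower (-4.38, SE 0.41), and Saa1 (-4.44) and Saa2 (-3.99) were lower as well. Gsdmc2 was also lower (-5.28, SE 0.32), with a mean below the filter's level in Mex3a+ Lgr5- cells. Apcdd1 was 5.96-fold higher (2.58, SE 0.35) and Adam12 5.44-fold higher (2.44, SE 0.46), beside Pnliprp1 (2.74), Pnliprp2 (2.50) and Rbms3 (2.25). Mex3a was 1.73-fold higher (0.79, SE 0.17, limma adjusted p = 0.00924) and Lgr5 2.42-fold higher (1.27, SE 0.20, limma adjusted p = 0.00214). By limma 649 genes were higher and 1476 lower, and 1366 and 2655 with the mouse as a block. The lower share of the calls was 69.5%, and 55.6% after a further quantile normalization or 55.0% after median centring. The count was 209 without mouse MKL347, 726 without mouse MKL367, 1246 without the Mex3a- Lgr5- array of mouse MKL347 and 1024 without the Mex3a+ Lgr5- array of mouse MKL367. Of the 12 named genes, 10 lost their call without mouse MKL347 (limma adjusted p between 0.0570 and 0.245), while Gsdmc2 and Slc26a3 kept it without any 1 mouse or array. Pnliprp1 also lost its call without the Mex3a- Lgr5- array of mouse MKL358 (0.0561) or MKL347 (0.0734) or the Mex3a+ Lgr5- array of mouse MKL367 (0.0704), and Saa2 without the last 2 of these (0.0538 and 0.0529).

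The Mex3a effects in Lgr5+ and in Lgr5- cells ran largely in parallel. They shared 299 genes higher (20.8 if independent) and 535 lower (70.9 if independent), and their log2 differences correlated across genes at r = 0.893 and rho = 0.782. Both effects were tested with the same estimate of each gene's spread, so the counts if independent may be too low a baseline. The interaction of Mex3a and Lgr5 status called 0 genes by limma, 0 with the mouse as a block, and 359 and 1078 genes had an unadjusted p under 0.05 in these fits. Without any interaction a share of 0.05 of the 12595 genes would be expected there. The count lies below that share in the main fit and above it with the block, so differences between the effects are not excluded. Without the Mex3a- Lgr5- array of mouse MKL347 the interaction called 1 gene. For Lgr5 the interaction was -0.92 (SE 0.28, limma adjusted p = 1; 0.351 with the mouse as a block).

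**Figure D3:**
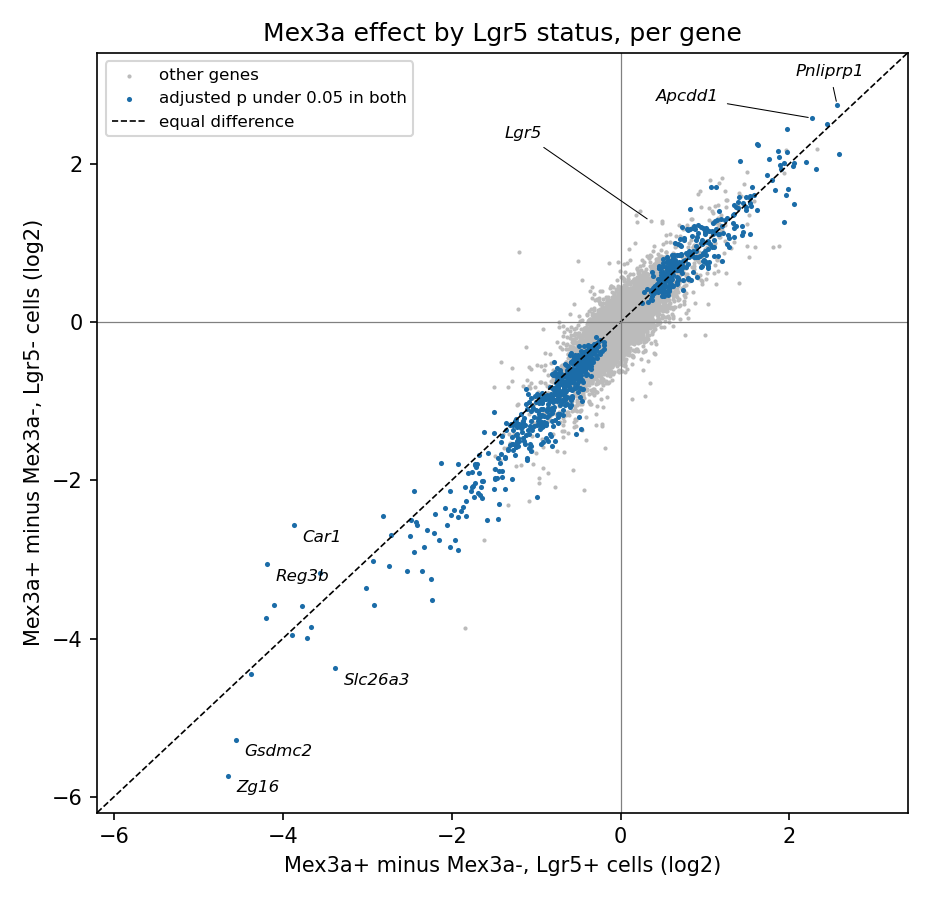
Log2 difference of each of 12595 genes between Mex3a+ and Mex3a- cells, in Lgr5+ cells (horizontal axis) and in Lgr5- cells (vertical axis), with genes past an adjusted p of 0.05 in both in blue and a dashed line for equal differences. Zg16 lay at -4.65 and -5.73, and Apcdd1 at 2.27 and 2.58; the correlation across genes was 0.893.

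In Mex3a- cells, Lgr5 status went with Vwa2 4.48-fold higher (log2 difference 2.16, SE 0.20, limma adjusted p = 0.00221), Lgr5 4.02-fold higher (2.01, SE 0.20, limma adjusted p = 0.00221), Rnf157 2.55-fold higher (1.35, SE 0.17, limma adjusted p = 0.0245) and Fhl1 lower (-1.01, SE 0.14, limma adjusted p = 0.0420), from 3 arrays against 3. The mean of Fhl1 in Mex3a- Lgr5+ cells, 3.91, lay below the filter's level of 4.40. These 4 were the only calls by limma. With the mouse as a block 102 genes were higher and 102 lower, among them Prkd1 (1.57), Muc1 (1.25), Cyp2d34 (-1.42), Itih5 (-1.34), Slc26a3 (-1.24) and Nlrp9b (-1.20). In Mex3a+ cells Lgr5 had a log2 difference of 1.09 (SE 0.20) and Car1 of -1.97 (SE 0.25), with limma adjusted p of 0.584 and 0.0539. There 0 genes passed by limma, with 376 at an unadjusted p under 0.05. With the mouse as a block 7 were higher and 2 lower. By that fit Lgr5 (limma adjusted p = 0.0289), Vwa2, Scara3, Thbs2 and Col9a3 were the 5 largest rises, and Car1 and Steap1 the falls.

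The few calls by Lgr5 status within a Mex3a state moved with single mice and arrays. In Mex3a- cells there were 0 calls without mouse MKL347 or mouse MKL358 (limma, adjusted p of the 4 genes between 0.0931 and 0.453 and between 0.121 and 0.330) and 2 without mouse MKL367 (Rnf157 0.291 and Fhl1 0.602). There were 2 without the Mex3a- Lgr5+ array of mouse MKL358 or the Mex3a+ Lgr5- array of mouse MKL347, and 7 without the Mex3a- Lgr5- array of mouse MKL367. Vwa2 and Lgr5 kept their call without any 1 array. Rnf157 lost it without the Mex3a- Lgr5+ array of mouse MKL358 or any 1 of the Mex3a+ Lgr5-, Mex3a- Lgr5+ and Mex3a- Lgr5- arrays of mouse MKL347 (0.0537 to 0.158). Fhl1 kept it without the Mex3a+ Lgr5+ array of mouse MKL358 or any 1 of the Mex3a+ Lgr5+, Mex3a- Lgr5+ and Mex3a- Lgr5- arrays of mouse MKL347, but not without any other array (0.0688 to 0.228). In Mex3a+ cells 1 gene was called without mouse MKL367, 1 each without the Mex3a+ Lgr5+ or Mex3a+ Lgr5- array of mouse MKL358 (Car1, 0.0185 and 0.0353), and 1 without the Mex3a+ Lgr5+ array of mouse MKL367 (Scara3, 0.0385).

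Double positive cells were compared with double negative cells (3 arrays against 3), a contrast that holds both the Mex3a and the Lgr5 effect. Gsdmc2 was lower (log2 difference -5.36, SE 0.32), with a mean below the filter's level in double positive cells. Slc26a3 was 24.6-fold lower (-4.62, SE 0.41) and Krt20 27.9-fold lower (-4.80, SE 0.71), beside Zg16 (-5.43) and Saa1 (-5.19). Pnliprp1 (3.09), Pnliprp2 (2.84), Ltbp1 (2.68), Vim, an intermediate filament gene of mesenchymal cells (2.63), and Alb (2.53) were higher. Lgr5 was 5.14-fold higher (2.36, SE 0.20, limma adjusted p = 4.00e-05) and Mex3a 1.87-fold higher (0.90, SE 0.17, limma adjusted p = 0.00380). Crypt base stem cell genes rose as a list, with 11 of 31 higher, 5 lower and 15 not passing (11 and 5 adjusted over the list alone) and a median of 0.25 (camera adjusted p = 0.00651; adjusted p = 0.173 with an estimated correlation). By limma 976 genes were higher and 1423 lower, and 1756 and 2405 with the mouse as a block. The lower share was 59.3%, and 54.3% and 50.2% after quantile normalization and median centring. The count was 335 without mouse MKL347, 1019 without mouse MKL367, 1589 without the Mex3a- Lgr5- array of mouse MKL347 and 1433 without the Mex3a+ Lgr5+ array of mouse MKL367. Of the 12 named genes, 8 lost their call without mouse MKL347 (limma adjusted p between 0.0528 and 0.208), and Gsdmc2, Krt20, Slc26a3 and Lgr5 kept it.

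The single positive populations were compared as Mex3a+ Lgr5- against Mex3a- Lgr5+ cells (3 arrays against 3). Gsdmc2 was lower in the Mex3a+ Lgr5- cells (log2 difference -4.48, SE 0.32), where its mean lay below the filter's level, and Aqp4 was 9.68-fold lower (-3.28, SE 0.33), beside Zg16 (-4.96), Saa1 (-3.63) and Muc3 (-3.22). Apcdd1 was 5.32-fold higher (2.41, SE 0.35), beside Gstm7 (2.36), Alb (2.19), Pnliprp2 (2.10) and Prex2 (2.07). Colonocyte genes fell, 19 of 34 lower, 0 higher and 15 not passing (23 lower and 1 higher adjusted over the list alone), with a median of -0.88 (camera adjusted p = 3.80e-11, and 0.328 with an estimated correlation). The list of endothelial genes and that of genes raised by dissociation were called as well. The endothelial list lost its call without mouse MKL358 (camera adjusted p = 0.163). The dissociation list lost its call without the Mex3a+ Lgr5- array of that mouse (camera adjusted p = 0.351). Neither marker passed: Mex3a was 0.47 higher (SE 0.17, limma adjusted p = 0.125; 0.0283 with the mouse as a block), and Lgr5 had a log2 difference of -0.73 (SE 0.20, limma adjusted p = 0.0521; 0.00407 with the mouse as a block). Lgr5 passed without the Mex3a+ Lgr5+ array (0.0438) or the Mex3a- Lgr5- array (0.0490) of mouse MKL358, or the Mex3a- Lgr5- array of mouse MKL367 (0.0218).

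By limma 178 genes were higher and 514 lower in Mex3a+ Lgr5- than in Mex3a- Lgr5+ cells, and 846 and 1882 with the mouse as a block. The lower share of the calls was 74.3%, and 54.1% after a further quantile normalization or 57.2% after median centring. The count was 16 without mouse MKL347, 84 without mouse MKL367, 134 and 107 without the Mex3a- Lgr5+ arrays of mice MKL358 and MKL347, and 324 and 74 without the Mex3a+ Lgr5- arrays of mice MKL347 and MKL367. Of the 10 named genes that passed, 8 lost their call without mouse MKL347 (limma adjusted p between 0.0714 and 0.279), 3 without mouse MKL358 (0.0531 to 0.124) and 2 without mouse MKL367 (0.0514 to 0.102). Gsdmc2 and Aqp4 kept it without any 1 mouse or array. The Mex3a- Lgr5+ array of mouse MKL358 and the Mex3a+ Lgr5- arrays of mice MKL347 and MKL367 decided 4 of the 10 calls each (up to 0.139, 0.0678 and 0.155 without them), and the Mex3a- Lgr5+ array of mouse MKL347 decided 3 (up to 0.134). The Mex3a+ Lgr5- array of mouse MKL358 (0.0584), the Mex3a+ Lgr5+ (0.0528) and Mex3a- Lgr5- (0.0503) arrays of mouse MKL347 and the Mex3a- Lgr5+ array of mouse MKL367 (0.0634) decided 1 each.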

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

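The list test was fixed before the data were seen. The test of probe sets with several symbols or none was added after the data files had been opened. A difference between groups set apart 8 gene lists. For them the Mex3a effect differed between Lgr5+ and Lgr5- cells by the interaction test of camera with its preset correlation. For the same interaction 0 single genes passed by limma (359 at an unadjusted p under 0.05). DNA replication genes had a median Mex3a effect of -0.24 in Lgr5+ and -0.093 in Lgr5- cells (adjusted p of the difference 1.17e-05). Goblet cell genes had -0.81 and -1.12 (0.000251). Genes of the unfolded protein response had 0.031 and -0.16 (0.000346), and respiratory chain genes -0.27 and -0.36 (0.00508). Genes of drug handling had -0.43 and -0.62 (0.00640), crypt base stem cell genes 0.067 and 0.15 (0.0192), genes of the G2 and M phases -0.34 and -0.28 (0.0192), and genes raised by interferons 0.19 and -0.15 (0.0242). The means of the stem cell list, -0.12 and -0.047, had the opposite sign to its medians. The median difference also changed sign between mice MKL347, MKL358 and MKL367 for the stem cell list (-0.26, -0.0064 and 0.087) and the G2 and M list (0.047, -0.17 and -0.11). With an estimated correlation their adjusted p lay between 0.662 and 0.875, and fry called 0 of the 8 (adjusted p between 0.282 and 0.956). Without mouse MKL347 the stem cell list had an adjusted p of 0.121. Without mouse MKL358 the goblet list had 0.0990, the drug handling list 0.0990 and the G2 and M list 0.186. Without mouse MKL367 the G2 and M list had 0.166, the interferon list 0.145 and the respiratory chain list 0.145. When 1 array was left out, which was tried only after the data had been seen, the unfolded protein and respiratory chain lists kept their call without any array, and the other 6 lost it without at least 1 (adjusted p up to 0.770).

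A signal also lay in data that enter no comparison of genes, the probe sets with several gene symbols or none. Of 8482 above the filter, 1656 passed by limma for the average Mex3a effect, 898 higher and 758 lower. For the average Lgr5 effect 1 was higher and 1 lower. The Mex3a calls were 19.5% of these probe sets, against 27.2% of the named genes. The shares differ in kind, since each named gene stood for its brightest probe set alone.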

How the results depend on the processing

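The fit with the mouse as a random effect (correlation 0.363), the block with an estimated correlation for lists, and lists without 1 array were added after the data had been seen. Of the 9 counts, all but that of the interaction (0 by limma in both fits; 359 and 1078 genes at an unadjusted p under 0.05) rose by more than 1.5 times with the mouse as a block. They rose to 5192 for the average Mex3a effect, 227 for the average Lgr5 effect, 2772 and 4021 for the Mex3a effect in Lgr5+ and Lgr5- cells, 9 and 204 for the Lgr5 effect in Mex3a+ and Mex3a- cells, 4161 for double positive against double negative and 2728 for the single positive populations. Every gene called without the block was called with it. The random effect gave 107, 2437, 3790, 6, 87, 3866 and 2404 in the same order without the average Mex3a effect. Array weights gave 15 for the average Lgr5 effect, 2304 for the Mex3a effect in Lgr5+ cells, 1 and 13 for the Lgr5 effect in Mex3a+ and Mex3a- cells and 1923 for the single positive populations. The mean of all probe sets gave 8 for the average Lgr5 effect. For the Lgr5 effect in Mex3a+ cells (0 by limma, 376 at an unadjusted p under 0.05), no filter, a further quantile normalization and median centring gave 1 each. Leaving out 1 mouse or 1 array gave 1034 to 3498 for the average Mex3a effect and 0 to 7 for the average Lgr5 effect. It gave 19 to 1335 and 209 to 2179 for the Mex3a effect in Lgr5+ and Lgr5- cells, 0 to 1 and 0 to 7 for the Lgr5 effect in Mex3a+ and Mex3a- cells. It gave 335 to 2705 for double positive against double negative, 16 to 828 for the single positive populations and 0 to 1 for the interaction. The lowest count came without mouse MKL347 for both average effects, both Mex3a effects within a state of Lgr5, and the double and single positive comparisons. With 1 mouse fewer, groups of 2 were left, and limma's pooled spread carried the test. These fits also left out the pairing by mouse, so a lost call alone does not tell a smaller difference from a larger error. Of the reversed values, 4 belong to Mex3a where it had passed no test. Its Lgr5 effect in Mex3a+ cells was 0.11, but -0.071 with the mean of probe sets, -0.028 without mouse MKL367 and -0.031 without the Mex3a+ Lgr5+ array of mouse MKL367 (-0.031 to 0.24 over all left-out mice and arrays). Its interaction was -0.21, but 0.017 with array weights. As lists, neutrophil genes in the average Lgr5 effect reversed to 0.022 without the Mex3a- Lgr5- array of mouse MKL358 (-0.46 to 0.022 over left-out mice and arrays), and genes of hypoxia and glycolysis in the Lgr5 effect in Mex3a+ cells to 0.046 without the Mex3a+ Lgr5- array of that mouse (-0.10 to 0.046). Of the 107 list calls over all comparisons, 5 held with an estimated correlation, 48 by fry, 104 with the block, 1 with the block and an estimated correlation, 100 with the mean of probe sets, 98 without the filter, and 85, 87 and 88 without mice MKL347, MKL358 and MKL367. Without 1 array, 90 to 100 held. Of 202 gene results, 40 that the main fit did not call passed with the block, and some of those also passed in other settings. Array weights gave 6 such passes and a further quantile normalization 3. Some of the 202 were not called by the main fit and so had no call to lose. Among the called ones, 77, 15 and 25 lost their call without mice MKL347, MKL358 and MKL367. Apart from the left-out arrays, which make the test smaller, the cause was not tested. The number of arrays, and signal below the filter's level for genes such as Gsdmc2 in Mex3a+ cells (3.30 and 3.39 against 4.40), limit the precision. Clca4a, Cyp2d34, Fabp2, Fhl1, Itih5, Prss30, Scara3, Sox17, Trim30d and Wnt10a also had a mean below that level in at least 1 population.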

Other observations

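Chosen after values had been seen were the gene families below, both tests of single probe sets, the test of immune and stromal cells, and the test of pool size for genes of the G2 and M phases. The probe set test was first written for 3 genes together and then split, and a test that restated the median of the G2 and M list was set aside. For the average Mex3a effect, 47 families of genes with a shared symbol stem were looked at; 13 were called by camera with the preset correlation, adjusted over the 47, and 0 kept the call with an estimated correlation. Sox transcription factor genes rose, with 5 of 14 higher, 1 lower and 8 not passing, Sox11 (log2 difference 0.95) and Sox6 (0.84) among the higher and Sox13 (-0.47) lower (camera adjusted p = 0.00963; adjusted p = 0.367 with an estimated correlation). ADAM and ADAMTS metalloprotease genes rose, 7 of 22 higher, 0 lower and 15 not passing, Adam12 and Adamts4 (0.54) among them (camera adjusted p = 0.0411; adjusted p = 0.367 with an estimated correlation). S100A calcium-binding protein genes fell, 5 of 9 lower, 0 higher and 4 not passing, S100a1 (-1.18) and S100a10 (-0.87) among them (camera adjusted p = 0.00651; adjusted p = 0.455 with an estimated correlation). Gasdermin genes split, 4 of 7 lower and 2 higher, with Gsdmcl2 (-2.46) and Gsdmc (-2.98) beside Gsdmc2 among the lower and Gsdma (1.70) among the higher (camera adjusted p = 0.0402; adjusted p = 0.406 with an estimated correlation); after a further quantile normalization 1 was higher. Mitochondrial ATP synthase genes fell, 15 of 17 lower, 0 higher and 2 not passing, and 11 and 12 lower after the scalings (camera adjusted p = 2.86e-05; adjusted p = 0.306 with an estimated correlation). Without mouse MKL347 limma's adjusted p was 0.0583 for Sox6, 0.107 for Sox13 and 0.0603 for Gsdma, and without mouse MKL367 it was 0.0551 for Sox6 and 0.127 for Sox13.

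The pancreatic lipase-related genes Pnliprp1 and Pnliprp2 and the albumin gene Alb were higher in Mex3a+ cells. Their mean levels were 8.82, 10.04 and 8.67 against 6.16, 7.57 and 6.31. Pnliprp2 is also on the fixed list of genes of Paneth and deep crypt secretory cells, so expression by intestinal cells stays open for it. Other markers argue against cells or RNA of pancreas or liver. The median log2 Mex3a effect of 19 other acinar cell genes was 0.018 (95% bootstrap interval -0.11 to 0.10, with 0 higher and 1 lower). For 25 other hepatocyte genes it was -0.013 (-0.084 to 0.017, with 1 higher and 2 lower). The bootstrap intervals here and below resample the genes of a list, not the mice. A fault of the probe set of Pnliprp2 is argued against by 1 other probe set of the gene that passed in the same direction (2.27, limma adjusted p = 0.000676). For Pnliprp1 and Alb a probe set fault stays open, with 0 other probe sets to test it, so their rises may be real or a fault of the probe set. A difference of cell state between the sorted populations stays open as well, untested.

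Colonocyte and goblet genes, 61 together, had a median Mex3a effect of -1.06. All populations of a mouse had the same pool size, so pool size did not differ by Mex3a status. In mice MKL347 and MKL367, with pools of 2000 cells, the median was -1.20 (bootstrap interval over genes -1.40 to -0.98). The falls thus did not rest on the smaller pools of mouse MKL358. Immune or stromal cells in the Mex3a+ pools, as the source of these falls, are argued against by 2 sets of medians without the filter. Genes of epithelium in general had -0.27 (bootstrap interval over genes -0.52 to -0.13), and the highest of the immune and stromal lists was 0.086, for endothelium. After the filter the endothelial median was 0.092, and 0.13 without the Mex3a+ Lgr5- array of mouse MKL347 (camera adjusted p = 0.0135). The fibroblast list had 0.10 after the filter without the Mex3a- Lgr5+ array of mouse MKL367 (camera adjusted p = 0.0689). Yet 4 of 31 fibroblast genes were higher and 1 lower, 3 of 25 endothelial genes higher and 1 lower, and Vim was 1.98 higher. Those list counts come from the fit without the filter. After it 1248 of all 12595 genes were higher, a smaller share than among the endothelial genes after the filter, given above. Relative to each gene's mean, fibroblast genes lay between -0.03 and 0.13 on the Mex3a+ arrays. They lay at 0.76 on the Mex3a- Lgr5+ array of mouse MKL367 and between -0.27 and -0.17 on the other Mex3a- arrays. A small share of stromal cells in the Mex3a+ pools is still not excluded. A lower share of mature epithelial cells among Mex3a+ cells, or a lower expression of these genes within each cell, could both give this pattern, and no test here parts them.

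Genes of the G2 and M phases were lower in Mex3a+ cells. All populations of a mouse had the same pool size, so pool size did not differ by Mex3a status. In the mice with pools of 2000 cells the median of these genes was -0.27 (bootstrap interval over genes -0.43 to -0.19). The fall thus did not rest on the smaller pools of mouse MKL358. The 3' to 5' difference of control probe sets between Mex3a+ and Mex3a- arrays was 0.012 (-0.045 to 0.069 over mice), which gave no sign of a difference. After amplification these probe sets are a limited sign of RNA integrity, so they cannot exclude it as a source of the fall. A lower share of dividing cells may underlie the fall; it was not tested, since no measure of division other than these transcripts was used here.

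Other splits of the same arrays were counted in a model without the interaction, which calls 3580 genes for the average Mex3a effect, against 3422 in the report's model. Of 100 splits of the 12 arrays into 6 and 6, 1, the real one, gave as many genes, and the highest other gave 2089, which argues against chance as the source of that count. That other split put 5 of the 6 Mex3a+ arrays on 1 side; among the 29 splits that part as many pairs of the same mouse, the highest other gave 1. For the average Lgr5 effect, 2 of 99 splits gave at least the real count of 5, a share under 0.05. The highest other gave 30 and had all 4 arrays of mouse MKL358 on 1 side, which points to the structure of the samples by mouse; among 28 splits that part as many pairs it was 1, and the count with the mouse as a block was 227. For the interaction the real count was 0 by limma, with 359 genes at an unadjusted p under 0.05. All 98 splits gave at least 0, as any split must, so they test nothing there. The highest other, with the same side for mouse MKL358, gave 10. The 3 against 3 comparisons allow 10 splits, too few for a share under 0.05. Their real counts and highest others were 1009 and 0 for the Mex3a effect in Lgr5+ cells and 2125 and 0 in Lgr5- cells. For the Lgr5 effect they were 0 and 9 in Mex3a+ cells (limma, with 376 genes at an unadjusted p under 0.05) and 4 and 2 in Mex3a- cells. All 10 splits gave at least the 0 of the Mex3a+ cells, as any split must. Double positive against double negative gave 2399 and 0, and the single positive populations 692 and 0.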
